A study of Mus musculus with 25 samples.

How the data were processed

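Gene expression was measured on Illumina mouse bead arrays in total RNA from ovarian follicles of CD-1 mice, 16 days old. The labels describe multilayered secondary follicles of 150 to 180 µm that were isolated mechanically, enclosed singly in alginate and cultured with 10 mIU/ml FSH, 1 mg/ml fetuin and 5 µg/ml insulin. At each time point 20 to 40 follicles were pooled, released with alginate lyase and frozen, RNA was extracted on small columns, and amplified RNA carried a biotin label. Follicle arrays came from day 0 (5 repeats) and from days 2, 4, 5, 6 and 8 of culture (3 repeats each), and 5 further arrays were labelled brain reference. The design text speaks of 8 samples in triplicate and the protocol of 3 independent experiments per group, whereas the arrays form 7 groups of 5 or 3 repeats. No slide or chip position was given in the sources used here.

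The deposited table of signals held 25697 probes. Per the file headers it gave for each probe and array the mean bead signal as an intensity, the standard error of that intensity, a detection p (p_value) and the number of beads (other unit: a count of beads). The detection p-values were deposited as computed per array for each probe, before any step taken here, and the software was not given in the sources used here. These intensities were deposited without normalization, and their distributions differed between arrays. A further table by the authors held 23286 of the same probes as log2 values, with array medians from 7.84 to 7.89, so they had been normalized between arrays; the method was not given in the sources used here. All 20 follicle columns of the authors' log2 table were tested against the signals over 4486 bright probes, and each correlated best with the signals of its own sample, the lowest correlation being 0.988. Array medians of the deposited intensity lay between 92.4 and 168, the median number of beads between 38 and 40, and the median standard error of a signal between 3.71% and 5.19% of it. For arrays, precision is limited by the number of arrays per group.

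Signals of the 20 follicle arrays were corrected for background and quantile normalized with neqc in limma 3.58.1 (R 4.3.3), with background estimated from the detection p and an offset of 16, and taken to log2. Probes with a detection p under 0.05 on at least 3 of the 20 arrays were kept, which left 14490 probes, and the probe with the highest mean was taken for each symbol, which left 10688 genes. Symbols were brought up to date with the mouse RefSeq gene table (GRCm38.p6), which served here for symbols and gene spans only: 14307 of 18138 symbols were current, 2906 were updated through a unique synonym, 903 were kept as given, and 22 had been turned into dates or numbers by a spreadsheet, of which 14 were among the genes tested. Probes of Hba-a1, Hbb-b1, Hbb-b2, Ugt1a10, Aldh1a7 and Aldh1a1 belong to families of near-identical genes, and their signals can come from more than 1 member.

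A linear model with 1 mean per day was fitted to all 20 arrays with limma (lmFit, eBayes), so that the 6 days shared their estimate of spread, and p values were adjusted by Benjamini and Hochberg over all genes tested, with a threshold of 0.05. Each day was compared with day 0, each cultured day with the one before, and day 8 with day 2; a moderated F test covered all 6 days. A day on which no array had a detection p under 0.05 for a gene was treated as not above background. A fold against such a day is a lower bound, computed against the lowest detected level of each array, and is written as "at least". List medians were computed from fitted changes and again with such members held at that bound.

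Before the data were examined, the comparisons, the 24 gene lists and the rule for naming genes were fixed. Named were the 10 genes with the largest rise and the 10 with the largest fall for day 2 and day 8 against day 0 and for day 8 against day 2, and 3 in each direction for the other comparisons, among genes past the threshold with no overlap between the arrays of both days. From each list up to 4 members that passed with the largest change and up to 2 that did not pass with the highest mean were added for the 3 main comparisons. Genes without a symbol and RIKEN or Gm names were passed over. The lists covered granulosa cells (antral with oestradiol synthesis, and preantral), theca and androgen synthesis, cumulus expansion with ovulation and luteinisation, the oocyte, cholesterol synthesis and uptake, the cell cycle, basement membrane, fibrillar collagen and stromal matrix, matrix proteases, glycolysis and hypoxia, oxidative stress, the unfolded protein and amino acid response, heat shock, immediate early genes, YAP targets, p53 and apoptosis, the interferon response, and markers of macrophages, endothelium, smooth muscle, red blood cells, ovarian surface epithelium and brain. Adamts1 was the only gene shared by a pair of lists. Lists were tested against all other genes with camera at a preset correlation of 0.01, adjusted over the 24 lists within a comparison, and again with an estimated correlation; fry was run beside it.

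The procedure was tested on simulated data with the same design and spread before the comparisons were run. Of 70 genes changed by 2 on the log2 scale, 95.7% were recovered for day 8 against day 0 and 92.9% for day 8 against day 2; of 60 genes changed by 1, 81.7% and 73.3%; and of 70 genes changed by 0.5, 22.9% and 8.57%. Among 10469 unchanged genes, 6, 4 and 0 were called for day 8 against day 0, day 8 against day 2 and day 2 against day 0. A list of 19 genes shifted by 0.5 was found with an adjusted p of 2.28e-16 against day 0 and 3.43e-12 against day 2, with 0 of the 23 other lists called. Genes were drawn independently of one another, so this run does not test lists whose members vary together. In the real data, other groupings of the arrays of both days gave up to 15 lists called for day 2 against day 0.

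The titles of the 5 day 0 arrays mark them as repeats of a reference, in the same scheme as the arrays labelled brain reference, whereas the cultured arrays are titled by day. The 5 day 0 arrays may therefore be repeats of 1 pool, and the sources used here do not say whether they came from separate pools of follicles. In that case p values against day 0 would be too small, since the spread at day 0 would be technical. That spread also enters the estimate shared by the 6 days, so p values between cultured days could be too small as well. The median SD of a gene on the log2 scale was 0.164 at day 0 and 0.177 among the arrays labelled brain reference. On the cultured days it lay between 0.178 and 0.262. By the median SD, day 0 arrays thus varied no more than the other reference repeats. Between pairs of day 0 arrays, the variance of 2704 bright probes was 1.99 to 15.8 times that of bead noise. Between pairs of arrays labelled brain reference it was 1.74 to 4.39 times, so by this measure some day 0 pairs varied more. Neither measure settles whether the day 0 arrays were 1 pool. The day 0 arrays were counted as 5 samples and, in an alternative, as 1 sample. Repeat numbers did not pair arrays of different days throughout: deviations from day means correlated above 0.1 for 15 of 45 pairs of the same number, with a mean correlation of 0.00519. These correlations ranged from −0.423 to 0.559, and for 9 of 20 arrays the best match had the same number. A pairing of part of the arrays stays open, and the repeat number entered only as an alternative.

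Alternatives tried were no background correction, median scaling without quantile normalization, the authors' log2 values, an offset of 50, no filter or a stricter filter on dim probes (a detection p under 0.01 on every array of a day), all probes, the repeat number as a block, normalization with all 25 arrays, array weights, an intensity trend in the prior, an absolute log2 change of at least 1, a fit to the compared days only, day 0 averaged and counted as 1 sample, and each array left out in turn. A fit without day 6 repeat 1 and day 0 repeat 4, and a covariate made from 123 ribosomal protein and respiratory chain genes (the short-transcript index), were added after the data were seen. The arrays labelled brain reference were normalized with the follicle arrays and compared with day 0 only as a check of the labels. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Some members of the gene lists that the rule names are not reported here.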

Results

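Transcript levels were measured on 25 bead arrays: 20 from mouse ovarian follicles before and during culture in alginate, and 5 labelled brain reference. The follicle arrays comprised day 0, taken before culture (n = 5), and days 2, 4, 5, 6 and 8 of culture (n = 3 each). Between 44.2% and 51.3% of probes were detected on a follicle array and between 41.7% and 44.7% on an array labelled brain reference. Within a day, the median standard deviation of a gene was 0.16 on the log2 scale at day 0, 0.18 at day 2, 0.21 at day 4, 0.22 at day 5, 0.26 at day 6 and 0.21 at day 8. The series asks how gene expression in the follicle changes as it matures in vitro, and 5339 of the 10688 genes tested differed between the 6 days in the moderated F test. With day 0 averaged and counted as 1 sample, 2662 did. The size of a change depended on the scaling. In the authors' values 235 of 338 called changes of named genes were more than 1.5 times smaller than printed here, and without background correction 128 of 357 were.

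**Figure D1:**
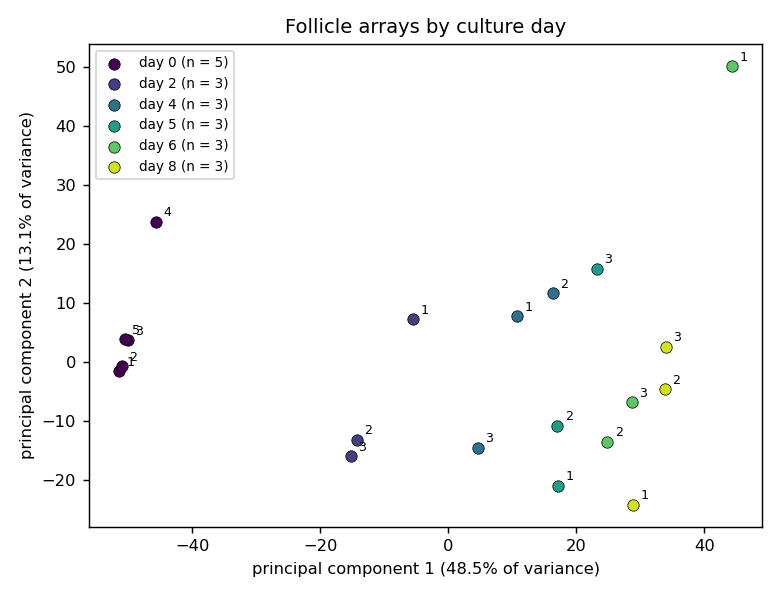
Each point is a follicle array (n = 5 at day 0, 3 on every other day), numbered by repeat and placed by its first (x, 48.5% of variance) and second (y, 13.1%) principal components of all genes tested, in units of log2 intensity. Days up to day 5 follow one another along the first component and days 6 and 8 overlap there, and day 6 repeat 1 lies apart on the second, at 50.2.

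After 2 days of culture, genes of cholesterol synthesis and of antral granulosa cells were higher than at day 0, and red blood cell, interferon response, immediate early and ovulation genes were lower. The largest single changes were those of Saa3 upward and Hba-a1 downward. Saa3, an acute-phase apolipoprotein, rose from 6.54 ± 0.20 (SD, n = 5) at day 0 to 13.08 ± 0.47 (n = 3) at day 2, a log2 change of 6.54 (SE 0.38, adjusted p = 2.69e-10). Inhba, which encodes the beta A subunit of activin and inhibin, rose 11.9-fold, from 9.35 ± 0.09 to 12.93 ± 0.37 (SE 0.16, adjusted p = 7.19e-12). Hba-a1, an alpha globin, fell by 5.38 (SE 0.12, adjusted p = 1.68e-16), and Rsad2, an interferon-induced antiviral enzyme, fell by 4.28. This comparison covers the first 2 days of culture: 2688 genes (25.1%) changed, 1293 upward and 1395 downward. Follicles of both days had been isolated, so effects of isolation cannot be told apart from those of culture.

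The other large rises at day 2 were those of Spp1 (3.97), which encodes osteopontin, the complement component C3 (3.96), Sectm1b (3.71), Adam23 (3.46), the retinol-oxidising enzyme Adh1 (3.33) and the glutathione transferase Gsta3 (3.21). Hsd11b1, which regenerates active glucocorticoid, and the glucuronosyltransferase Ugt1a10 were not above background at day 0 and were at least 13.3-fold and at least 12.1-fold higher at day 2. Falls after Hba-a1 and Rsad2 were led by Areg (18.4-fold lower), the EGF-like ligand amphiregulin, the plasminogen activator Plau (−3.82), Tnfrsf12a (−3.66), the pyruvate dehydrogenase kinase Pdk4 (−3.31), Mfap4 (−3.26), Ier3 (−3.14) and the interferon-induced Usp18 (−3.14). Edn2, encoding endothelin 2, was at least 9.21-fold lower and no longer above background.

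Genes of cholesterol synthesis and uptake rose together at day 2. Of 19 measured, 16 rose and none fell (18 rose adjusted over the list alone), among them Lss (1.86), Nsdhl (1.72) and Mvd (1.60), enzymes of the sterol pathway, and the sterol carrier Stard4 (1.67). Cyp51 (0.59) and Insig1 (−0.42) did not pass. Their median log2 change was 1.10, 0.96 with members not above background held at their bound, 0.40 in the authors' values and 0.59 without background correction (camera adjusted p = 2.40e-12). Antral granulosa genes were also higher, 7 of 15 rising and none falling (8 rose adjusted over the list alone; median 0.49, camera adjusted p = 1.66e-05). Among them were Inhba and the FSH receptor Fshr (1.15), while Inha (0.33) and Fst (0.38) did not pass. Prkar2b (1.13), a kinase subunit induced by FSH, passed as well, though not with the authors' values, without day 2 repeat 1 or with day 0 counted as 1 sample.

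Genes of cumulus expansion and ovulation were lower at day 2: 8 of 12 fell and 1 rose (9 and 1 adjusted over the list alone; median −0.87, or −0.33 in the authors' values and −0.53 without background correction, camera adjusted p = 5.29e-06). Areg, Edn2, the ligand Btc (−2.21) and Cited4 (−2.09) fell most. Immediate early genes fell in 11 of 18 cases with no rise (15 fell adjusted over the list alone; median −0.74, camera adjusted p = 5.84e-07). Falls were led by Ier3, Atf3 (−2.75) and the phosphatase gene Dusp1 (−1.32), while Egr1 (−0.25) did not pass. Of 22 genes of glycolysis and hypoxia, 12 fell and none rose (14 adjusted over the list alone; median −0.45, or −0.28 in the authors' values, camera adjusted p = 1.74e-06). The falls included Ankrd37 (−2.43), Ndrg1 (−1.39), the angiogenic factor Vegfa (−1.22) and the glucose transporter Slc2a1 (−1.17). Heat shock genes fell in 4 of 11 cases, among them Hspa1a (−2.18) and Hsph1 (−1.28), with none rising (4 fell adjusted over the list alone; median −0.41, camera adjusted p = 0.00245). The interferon response list fell in 8 of 12 members with none rising (8 adjusted over the list alone; median −1.12, or −0.32 in the authors' values and −0.66 without background correction, camera adjusted p = 1.04e-06), and its leading members Rsad2, Usp18, Ifit3 (−3.11) and Mx2 (−1.86) are antiviral genes.

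Oocyte genes were lower by day 2, with 12 of 24 falling and none rising (15 adjusted over the list alone; median −0.63, camera adjusted p = 1.22e-06). Fgf8 (−1.02) and the zona pellucida genes Zp1 (−0.96) and Zp3 (−0.92) fell most, although none of these 3 passed with day 0 counted as 1 sample, and Ooep (−0.54) and Oosp1 (−0.41) did not pass. The list was not called with an estimated correlation (adjusted p = 0.143 with an estimated correlation), whereas fry, which tests a list by itself, gave an adjusted p of 0.000702. Unfolded protein and amino acid response genes fell in 8 of 19 cases and rose in 1 (the same counts adjusted over the list alone; median −0.36, or −0.21 in the authors' values, camera adjusted p = 0.00245, but adjusted p = 0.0515 with an estimated correlation), Ppp1r15a (−1.57) and Chac1 (−1.09) falling most. In the cell cycle list 5 of 27 rose, including the replication genes Mcm7 (0.94) and Cdc6 (0.70), and 2 fell, including the mitotic checkpoint gene Bub1b (−0.77), with the same counts adjusted over the list alone. The camera adjusted p was 0.0262 (adjusted p = 0.0515 with an estimated correlation), and it rose to 0.0747 with the authors' values, 0.0585 with array weights and 0.0592 without day 2 repeat 1 (0.00439 to 0.0747 over all alternatives). Mcm7, Cdc6 and Bub1b did not pass with day 0 counted as 1 sample, nor did Mcm7 without day 2 repeat 1 (adjusted p = 0.0823, within 0.00304 to 0.324 over all alternatives).

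All 5 measured red blood cell genes fell at day 2 (5 adjusted over the list alone; median −1.60, or −0.33 in the authors' values and −0.72 without background correction, camera adjusted p = 5.84e-07). Of 6 markers of ovarian surface epithelium 4 fell with none rising (4 adjusted over the list alone; median −0.90, or −0.28 in the authors' values and −0.53 without background correction, camera adjusted p = 0.00449, adjusted p = 0.0515 with an estimated correlation), among them the keratins Krt18 (−2.38) and Krt8 (−1.36). Among endothelial markers 4 of 13 fell, including the receptor Tek (−1.07), and Vwf (1.41) rose (5 and 1 adjusted over the list alone; camera adjusted p = 0.0364, adjusted p = 0.272 with an estimated correlation). That call was lost with the stricter filter (0.0535), with array weights (0.0683), without day 0 repeat 5 (0.0525) and without day 2 repeat 1 (0.0891), within 0.00439 to 0.0891 over all alternatives. Smooth muscle markers fell in 4 of 7 cases, led by Rgs5 (−1.14) and Myh11 (−1.01), and rose in 1, the same counts adjusted over the list alone (camera adjusted p = 0.0459, adjusted p = 0.305 with an estimated correlation). This call was lost under 13 of 34 alternatives, with adjusted p from 0.0189 to 0.133. Vwf and Myh11 did not pass with day 0 counted as 1 sample. Of 4 brain list members measured, 3 rose, among them Olfm1 (1.42) and Aldoc (1.28), and Mbp (0.10) did not pass (3 rose adjusted over the list alone; camera adjusted p = 0.00515, or 0.105 with no filter on dim probes and 0.00339 to 0.105 over all alternatives). Aldoc did not pass with the authors' values (adjusted p = 0.0592) or with day 0 counted as 1 sample (adjusted p = 0.144, within 2.51e-06 to 0.144 over all alternatives).

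The remaining lists went both ways at day 2 and were not called. Among theca and androgen genes 3 of 13 rose and 3 fell (3 and 3 adjusted over the list alone; median 0.09, mean −0.13, camera adjusted p = 0.650). Aldh1a1 (1.39) rose, Cyp17a1, the androgen-forming lyase, fell by 1.87 (adjusted p = 5.06e-07), and Bmp4 was at least 3.62-fold lower. Matrix proteases and inhibitors changed in 15 of 16 cases, 9 rising and 6 falling (9 and 7 adjusted over the list alone; median 0.50, mean −0.05, camera adjusted p = 0.650). Mmp11 (1.64) and Timp2 (1.53) rose and Plau fell. Basement membrane genes rose in 3 and fell in 4 of 15 cases (3 and 5 adjusted over the list alone; median 0.09, mean −0.11, camera adjusted p = 0.733), Col15a1 (1.38) and Tinagl1 (4.94-fold lower) changing most. Stromal matrix genes rose in 5 and fell in 3 of 18 cases (6 and 3 adjusted over the list alone; median 0.07, mean −0.04, camera adjusted p = 0.753), and Mfap5 was at least 5.31-fold lower. Preantral granulosa genes rose in 1 and fell in 2 of 12 cases (2 and 3 adjusted over the list alone; camera adjusted p = 0.721), with Kctd14 (−1.53) falling most and a median of −0.04 that was 0.01 in the authors' values. The p53 list rose in 5 and fell in 2 of 15 cases (7 and 4 adjusted over the list alone; camera adjusted p = 0.214). Ccng1 (1.54) and Zmat3 (1.42) rose, Gadd45a (−1.97) fell and Cdkn1a was at −0.08. Oxidative stress genes split 3 and 3 among 19 (5 and 3 adjusted over the list alone; camera adjusted p = 0.324), Gstm1 (1.45) and Nqo1 (1.44) rising. YAP targets rose in 1 and fell in 3 of 11 cases (1 and 5 adjusted over the list alone; camera adjusted p = 0.183), Ccn2 (−2.75) falling most. Macrophage markers rose in 2 and fell in 3 of 12 cases, the same counts adjusted over the list alone (camera adjusted p = 0.402). The number of genes changed at day 2 depended on how day 0 was counted, and the titles of the 5 day 0 arrays mark them as repeats of a reference, so they may be repeats of 1 pool. Of all genes 498 passed with day 0 as 1 sample, all of them among the 2688 with the same direction, and 4802 with array weights. An absolute log2 change of at least 1 was reached by 615 genes.

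By day 8, antral granulosa, theca and androgen, and cholesterol genes were higher than at day 0, while oocyte and cell cycle genes and the gene of anti-Müllerian hormone were lower. Comp, a pentameric cartilage matrix protein, was not above background at day 0 (4.92 ± 0.06, n = 5) and stood at 11.07 ± 0.26 (n = 3) at day 8, at least 51.3-fold higher (adjusted p = 1.47e-12). Grem1, the BMP antagonist gremlin, rose 51.5-fold (log2 5.69, SE 0.18, adjusted p = 3.04e-14) and Inhba by 5.39 (SE 0.16, adjusted p = 1.28e-14). Lhcgr, the LH receptor, rose 20.2-fold, from 6.54 ± 0.17 to 10.88 ± 0.09 (SE 0.14, adjusted p = 3.04e-14). Amh, a product of growing preantral and small antral follicles, was at least 21.0-fold lower and no longer above background at 4.58 ± 0.10. This comparison spans the whole culture: 4637 genes (43.4%) changed, 2197 upward and 2440 downward.

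Other leading rises at day 8 were those of Adam23 (5.12), the adhesion molecule Vcam1 (4.91), the fatty acid desaturase Scd1 (4.59), Gpnmb (4.36) and Adh1 (4.32). Aldh1a7 was at least 16.2-fold higher than at day 0, where it was not above background. Hba-a1 was at least 64.1-fold lower. The vesicular monoamine transporter Slc18a2 fell by 5.00 (SE 0.31, adjusted p = 1.97e-10), and Rsad2 (−4.22), Cited4 (−4.12), Chac1 (−3.97) and Phlda1 (−3.84) followed. The chemokines Ccl4 and Cxcl10 and the germ-cell lactate dehydrogenase Ldhc were at least 16.7-fold, at least 12.4-fold and at least 7.78-fold lower.

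**Figure D2:**
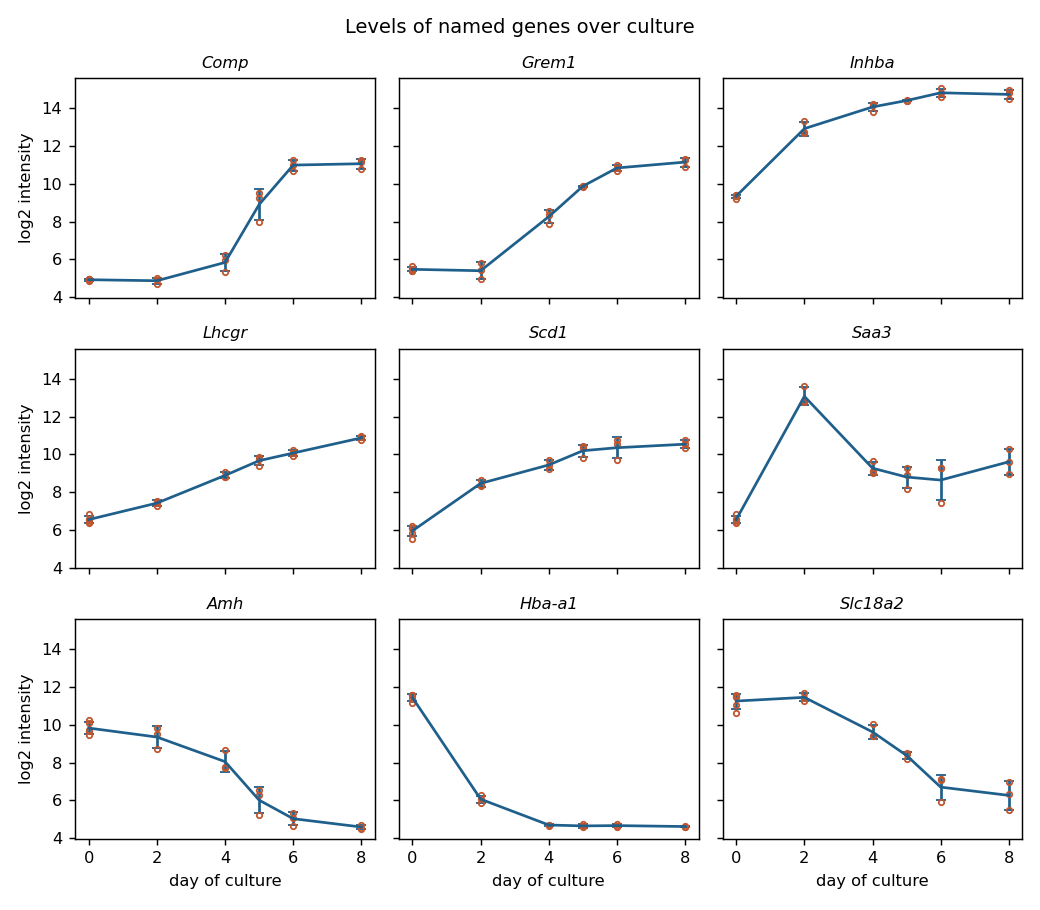
Log2 intensity (y) of 9 named genes against day of culture (x), with open circles for arrays and lines with bars for the mean ± SD of each day (n = 5 at day 0, 3 on other days). Inhba and Lhcgr were higher on each cultured day than at day 0, Comp went from 5.84 at day 4 to 11.00 at day 6, and Saa3 was highest at day 2, at 13.08.

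Antral granulosa genes rose in 10 of 15 cases and fell in 1 by day 8 (the same counts adjusted over the list alone; median 1.26, or 0.81 in the authors' values, camera adjusted p = 1.32e-05). Beside Inhba and Lhcgr these included Cyp19a1, the aromatase that forms oestradiol, which rose 8.58-fold (adjusted p = 5.78e-10), and Fshr, which rose 7.21-fold, while Inha (0.45) and the cyclin Ccnd2 (0.12) did not pass. Theca and androgen genes rose in 8 of 13 cases and fell in 2 (9 and 2 adjusted over the list alone; median 0.91, or 0.35 in the authors' values and 0.57 without background correction, camera adjusted p = 0.0104). Aldh1a1 (3.28), Hsd3b1 (1.89), the side-chain cleavage enzyme Cyp11a1 (1.85) and Insl3 (1.74) rose most. In the cholesterol list 18 of 19 rose and none fell (18 adjusted over the list alone; camera adjusted p = 7.27e-14), with a median of 1.93, 1.78 with members not above background held at their bound and 0.95 in the authors' values. Nsdhl (2.78) and Lss (2.43) were among those that rose.

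Of 24 oocyte genes, 23 fell and none rose by day 8 (23 adjusted over the list alone; median −1.95, camera adjusted p = 1.37e-13). Fgf8 (−2.79), the growth factor Bmp15 (−2.50), Zp3 (−2.48) and Zp1 (−2.47) fell most, and Sohlh1 (0.04) did not pass. Cell cycle genes fell in 15 of 27 cases with none rising (18 adjusted over the list alone; median −0.64, camera adjusted p = 8.67e-06). Bub1b (−1.61), Birc5 (−1.19) and Mcm5 (−1.19) fell most, with Cdk1 at −0.30. Unfolded protein and amino acid response genes fell in 10 of 19 cases with none rising (10 adjusted over the list alone; median −0.65, or −0.33 in the authors' values, camera adjusted p = 0.00109). Chac1, Psat1 (−1.91) and Asns (−1.54) belong to the amino acid branch, and the chaperone Hsp90b1 was at 0.16. Heat shock genes fell in 6 of 11 cases and rose in 1 (the same counts adjusted over the list alone; median −0.56, camera adjusted p = 0.024), with Hsph1 (−2.20) and Hspa1a (−1.92) falling most.

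Cumulus and ovulation genes fell in 7 of 12 cases and rose in 2 by day 8 (7 and 2 adjusted over the list alone; camera adjusted p = 0.0073), with a median of −1.01, −0.93 at the bound, −0.33 in the authors' values and −0.61 without background correction. Areg (−3.42) and Edn2 (−3.23) fell, whereas the prolactin receptor Prlr rose 15.2-fold. The interferon list fell in 8 of 12 cases with none rising (8 adjusted over the list alone; median −1.21, or −0.51 in the authors' values, camera adjusted p = 1.86e-05), led by Rsad2, Usp18 (−3.47) and Ifit3 (−3.15). Red blood cell genes fell in 5 of 5 cases (5 adjusted over the list alone; camera adjusted p = 7.62e-05), with a median of −1.78, −1.34 at the bound, −0.28 in the authors' values and −0.80 without background correction. Surface epithelium markers fell in 4 of 6 with none rising (4 adjusted over the list alone; median −1.19, or −0.31 in the authors' values and −0.62 without background correction, camera adjusted p = 0.00206), Krt18 (−3.14) falling most. Smooth muscle markers fell in 6 of 7 cases with none rising (6 adjusted over the list alone; camera adjusted p = 0.000265, adjusted p = 0.0553 with an estimated correlation), with a median of −1.51, −1.16 at the bound and −0.54 in the authors' values. Myh11 (−2.16) fell most. Endothelial markers fell in 8 of 13 cases and rose in 2 (9 and 2 adjusted over the list alone; median −0.79, or −0.27 in the authors' values and −0.52 without background correction, camera adjusted p = 0.0201, adjusted p = 0.209 with an estimated correlation), the VEGF receptor Flt1 (−2.00) and Eng (−1.77) among the falls. Cd34 (1.40) rose. Of the brain list, 3 of 4 rose, among them Aldoc (3.31) and Olfm1 (2.22), and Mbp (−0.14) did not pass (3 adjusted over the list alone; camera adjusted p = 0.00206).

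The remaining lists were not called for day 8 against day 0. Macrophage markers rose in 6 of 12 cases and fell in 3 (6 and 3 adjusted over the list alone; camera adjusted p = 0.235, or 0.025 with the stricter filter and 0.025 to 0.305 over all alternatives). The lysozymes Lyz2 (3.86) and Lyz1 (3.71) rose most and Cd14 (−1.46) fell. Immediate early genes rose in 2 and fell in 7 of 18 cases (2 and 7 adjusted over the list alone; camera adjusted p = 0.117, or 0.0361 without day 8 repeat 3 and 0.0361 to 0.253 over all alternatives). Ier3 (−3.01) and Socs3 (−1.93) fell most, and Fos was at 0.16. Preantral granulosa genes rose in 2 and fell in 3 of 12 cases (2 and 3 adjusted over the list alone; median 0.15, mean −0.77, camera adjusted p = 0.444). The falls included Amh and Slc18a2 and the rises Bmpr1b (1.28). Oxidative stress genes rose in 8 and fell in 4 of 19 cases (8 and 4 adjusted over the list alone; camera adjusted p = 0.172), Gpx3 (2.01) and Gsta4 (2.00) rising and Slc7a11 (−1.80) falling. The p53 list rose in 7 and fell in 4 of 15 cases (8 and 4 adjusted over the list alone; camera adjusted p = 0.142), Ccng1 (2.03), Trp53inp1 (1.88) and Bbc3 (1.46) rising. Matrix proteases rose in 7 and fell in 5 of 16 cases (8 and 6 adjusted over the list alone; camera adjusted p = 0.388). The cathepsin Ctsl (2.38) and Mmp9 (2.03) rose and Plau (−1.86) fell. Glycolysis and hypoxia genes split 7 and 7 among 22 (7 and 7 adjusted over the list alone; camera adjusted p = 0.654). Car9 (−1.72) fell and Eno1 (1.35) rose, though Eno1 did not pass with day 0 counted as 1 sample. Stromal matrix genes rose in 2 and fell in 6 of 18 cases (2 and 6 adjusted over the list alone; camera adjusted p = 0.163), Thy1 (−2.00) and Eln (−1.91) among the falls. Basement membrane genes rose in 1 and fell in 4 of 15 (1 and 3 adjusted over the list alone; camera adjusted p = 0.249). YAP targets rose in 3 and fell in 2 of 11 cases (3 and 2 adjusted over the list alone; median −0.23, mean 0.12, camera adjusted p = 0.841). With day 0 counted as 1 sample, 2113 genes passed for day 8, all of them among the 4637 with the same direction, and 1749 changed by at least 1 on the log2 scale.

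Day 8 against day 2 shows what changed once culture was under way: theca and androgen, cholesterol and glycolysis genes rose, and oocyte and cell cycle genes fell. The day 0 means do not enter this difference, although the day 0 arrays contribute to the estimate of spread. Comp was not above background at day 2 (4.87 ± 0.15, n = 3) and was at least 52.0-fold higher at day 8 (adjusted p = 4.27e-11). Grem1 rose 54.2-fold (log2 5.76, SE 0.20, adjusted p = 5.89e-13). Cyp17a1, which had fallen by day 2, rose 9.95-fold from day 2 to day 8 (log2 3.31, adjusted p = 2.01e-09), and Lhcgr rose 11.0-fold (adjusted p = 2.92e-11). Slc18a2 was 36.7-fold lower (SE 0.34 on the log2 scale, adjusted p = 3.27e-09), Amh was at least 15.1-fold lower, and Saa3 fell by 3.47 from its level at day 2. In all, 2396 genes (22.4%) changed, 1078 upward and 1318 downward.

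Further leading rises from day 2 to day 8 were those of the carboxylesterase Ces3 (4.31), Vcam1 (4.27), the bone sialoprotein Ibsp (3.89), Eppin (3.85), the transporter Slco2b1 (3.59) and the growth factor Igf2 (3.50). Insyn2b and the kallikrein Klk1 were at least 9.13-fold and at least 9.83-fold higher. The largest falls after Slc18a2 were those of the chemokine Ccl7 (−4.85), Mycl (−3.07), Tmem184a (−3.01) and Tex19.2 (−2.99), and Dpt, Ldhc and Foxq1 were at least 6.84-fold, at least 4.94-fold and at least 5.68-fold lower.

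Theca and androgen genes rose in 7 of 13 cases with none falling (7 adjusted over the list alone; camera adjusted p = 1.39e-05), with a median of 0.72, 0.52 with members not above background held at their bound, 0.21 in the authors' values and 0.37 without background correction. Beside Cyp17a1 they included Cyp11a1 (2.05), Insl3 (1.95) and Aldh1a1 (1.90), with Hsd3b1 at 0.73. Genes of glycolysis and hypoxia rose in 13 of 22 cases and fell in 1 (15 and 1 adjusted over the list alone; median 0.75, or 0.37 in the authors' values and 0.49 without background correction, camera adjusted p = 1.73e-06), among them Eno1 (1.70), Ankrd37 (1.51) and Pfkp (1.34). Cholesterol genes rose in 12 of 19 cases with none falling (16 adjusted over the list alone; median 0.58, or 0.35 in the authors' values, camera adjusted p = 1.18e-08), Cyp51 (1.34) and Nsdhl (1.06) among them. Antral granulosa genes rose in 7 and fell in 1 of 15 cases (8 and 2 adjusted over the list alone; median 0.50, camera adjusted p = 0.000223, adjusted p = 0.0529 with an estimated correlation). Cyp19a1 (2.19), Inhba (1.82) and Fshr (1.70) rose beside Lhcgr. Inha was at 0.12.

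Cell cycle genes fell in 20 of 27 cases from day 2 to day 8 with none rising (22 adjusted over the list alone; median −0.90, or −0.56 in the authors' values, camera adjusted p = 4.12e-13). Cdc6 (−1.65), Mcm7 (−1.58), E2f1 (−1.52) and Mcm6 (−1.45) fell most, while Cdc20 (−0.01) did not pass. Oocyte genes fell in 18 of 24 cases with none rising (20 adjusted over the list alone; median −1.33, or −0.87 in the authors' values, camera adjusted p = 6.42e-14), including Bmp15 (−2.07), Gdf9 (−1.89) and Fgf8 (−1.77), with Oosp1 (−1.07) not passing. Smooth muscle markers fell in 5 of 7 cases with none rising (6 adjusted over the list alone; median −1.12, or −0.30 in the authors' values and −0.51 without background correction, camera adjusted p = 0.000131, adjusted p = 0.071 with an estimated correlation), Tpm2 (−1.44) and Acta2 (−1.12) among them. Macrophage markers rose in 6 of 12 cases and fell in 1 (6 and 2 adjusted over the list alone; camera adjusted p = 0.004, adjusted p = 0.136 with an estimated correlation), with a median of 0.67, 0.47 at the bound, 0.18 in the authors' values and 0.30 without background correction. Lyz1 (2.60), Lyz2 (2.55) and Laptm5 (1.64) rose. Of the brain list, 3 of 4 rose, among them Aldoc (2.04) and Olfm1 (0.80) (3 adjusted over the list alone; camera adjusted p = 0.004, or 0.0732 with no filter on dim probes and 0.000678 to 0.0732 over all alternatives).

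A further 5 lists were called for day 8 against day 2 but lost the call in part of the alternatives. Immediate early genes rose in 8 and fell in 1 of 18 cases (8 and 2 adjusted over the list alone; median 0.57, or 0.31 in the authors' values, camera adjusted p = 0.0138, adjusted p = 0.251 with an estimated correlation), Jun (1.62), Dusp1 (1.32) and Fos (0.95) rising. The adjusted p was 0.0566 without day 2 repeat 1 and 0.0624 without day 8 repeat 3 (0.00308 to 0.0624 over all alternatives). Unfolded protein and amino acid response genes fell in 8 and rose in 3 of 19 cases (8 and 3 adjusted over the list alone; camera adjusted p = 0.0376, adjusted p = 0.2 with an estimated correlation), Chac1 (−2.89), Psat1 (−1.67) and Asns (−1.47) falling. Of 34 alternatives 9 ended the call, with adjusted p from 0.0102 to 0.157 over all, among them leaving out day 2 repeat 1 (0.099), day 6 repeat 1 (0.0593) or day 8 repeat 2 (0.0595). YAP targets rose in 4 of 11 cases with none falling (4 adjusted over the list alone; camera adjusted p = 0.0376, adjusted p = 0.152 with an estimated correlation), with the matricellular gene Ccn2 (2.38) and Crim1 (1.13) among them. The call ended under 5 alternatives, with adjusted p from 0.0161 to 0.0755 over all, among them leaving out day 8 repeat 3 (0.0624). Surface epithelium markers fell in 3 of 6 cases with none rising (5 adjusted over the list alone; camera adjusted p = 0.0313, adjusted p = 0.152 with an estimated correlation), Upk3b (−1.05) falling most. The median was −0.65, −0.51 at the bound, −0.13 in the authors' values and −0.31 without background correction. The call ended under 7 alternatives, with adjusted p from 0.00518 to 0.079 over all, among them leaving out day 2 repeat 3 (0.072) or day 6 repeat 1 (0.05). Stromal matrix genes fell in 4 of 18 cases with none rising (4 adjusted over the list alone; median −0.46, or −0.26 in the authors' values, camera adjusted p = 0.0313, adjusted p = 0.296 with an estimated correlation), Thy1 (−2.41) and Col6a2 (−1.50) falling most. Array weights (0.0519) and leaving out day 2 repeat 3 (0.0844) or day 8 repeat 2 (0.0731) ended the call (0.00531 to 0.0844 over all alternatives).

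The other 10 lists were not called for day 8 against day 2. Cumulus genes rose in 3 and fell in 1 of 12 cases (3 and 2 adjusted over the list alone; camera adjusted p = 0.204), Prlr (2.15) and the protease Adamts1 (1.71) rising and Cited4 (−2.04) falling. Matrix proteases rose in 7 and fell in 4 of 16 cases (7 and 4 adjusted over the list alone; camera adjusted p = 0.176), with Plau (1.96) and Ctsl (1.28) rising. Endothelial markers rose in 2 and fell in 5 of 13 cases (2 and 5 adjusted over the list alone; camera adjusted p = 0.176), Cd34 (1.31) higher and Flt1 (−1.52) lower. Preantral granulosa genes rose in 3 and fell in 3 of 12 cases (3 and 3 adjusted over the list alone; camera adjusted p = 0.482). Oxidative stress genes rose in 3 and fell in 1 of 19 (3 and 1 adjusted over the list alone; camera adjusted p = 0.390), Gpx3 (3.11) most. Of 15 p53 genes 4 rose with none falling (4 adjusted over the list alone; median −0.01, mean 0.15, camera adjusted p = 0.204), Trp53inp1 (1.24) most. Basement membrane genes rose in 1 and fell in 2 of 15 cases (1 and 2 adjusted over the list alone; camera adjusted p = 0.204). Heat shock genes rose in 1, Hspb1 (1.32), and fell in 1, Hsph1 (−0.92), of 11 (1 and 1 adjusted over the list alone; camera adjusted p = 0.588). The interferon list of 12 genes had a median of −0.14, or −0.12 at the bound (camera adjusted p = 0.216), with Bst2 at −0.83. In the red blood cell list Hba-a1 alone passed of 5, at least 1.54-fold lower (1 adjusted over the list alone; camera adjusted p = 0.204). Its median of −0.37 was 0.04 in the authors' values. With array weights 3885 genes passed for this comparison, and 885 changed by at least 1 on the log2 scale.

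**Figure D3:**
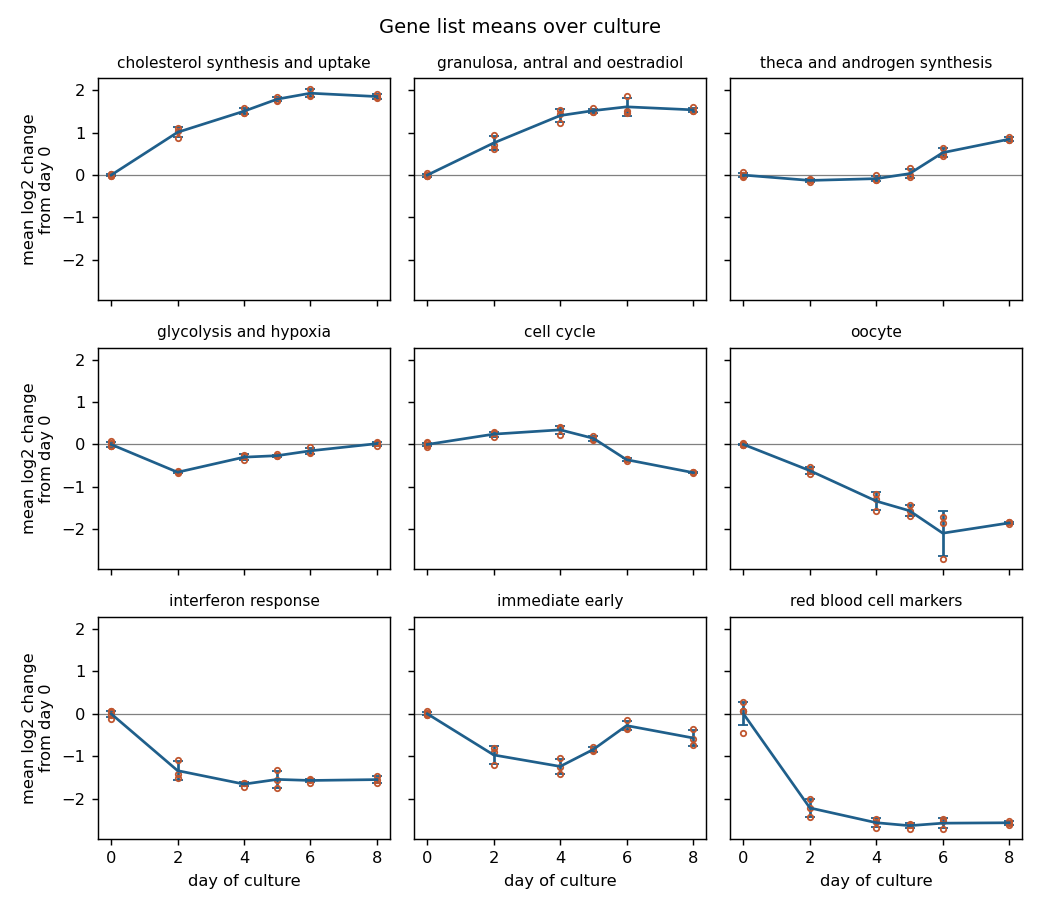
Mean log2 change from day 0 of the measured members of 9 gene lists (y) against day of culture (x), with open circles for arrays and lines with bars for the mean ± SD of the arrays of a day (n = 5 at day 0, 3 on other days). The mean of the cholesterol list stood at 1.01 at day 2 and 1.85 at day 8, and that of the oocyte list at −0.62 and −1.85.

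On the days between, many of the same genes led. At day 4, 3606 genes differed from day 0 (1639 higher, 1967 lower). Inhba (4.73), Adam23 (4.37) and Adh1 (3.53) rose most. Hba-a1 and Rsad2 were at least 63.0-fold and at least 15.9-fold lower, and Ccl4 was 18.4-fold lower. At day 5 the number was 3841 (1778 higher, 2063 lower), with Inhba (5.07), Adam23 (4.77) and Grem1 (4.41) rising most and Hba-a1, Ccl4 and Rsad2 at least 59.9-fold, at least 15.6-fold and at least 15.1-fold lower. At day 6 it was 4586 (2247 higher, 2339 lower), with Comp at least 48.8-fold higher and Inhba (5.48) and Grem1 (5.37) rising. Hba-a1 and Ccl4 were at least 63.6-fold and at least 16.6-fold lower, and Amh fell by 4.81. Under median scaling the balance shifted at day 4 to 849 higher and 2489 lower genes and at day 5 to 896 and 2775, and the median of all genes tested moved by −0.13 and −0.15 on the log2 scale. The surplus of falls on these days thus depended on the scaling. With day 0 counted as 1 sample, 1175, 1398 and 1938 genes passed for days 4, 5 and 6.

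Among the steps between cultured days, the most genes changed from day 2 to day 4. In that step 897 genes changed (326 higher, 571 lower), with Grem1 (2.87, adjusted p = 6.16e-08), the dopamine receptor Drd4 (2.70) and Slc38a3 (2.69) rising and Ccl7 (−4.35), Sectm1b (−3.83) and Saa3 (−3.81) falling. Median scaling gave 136 higher and 1011 lower genes, with the median of all genes at −0.17. A fit to the compared days gave 578 genes, array weights 2321, and leaving out day 2 repeat 2, day 2 repeat 3 or day 4 repeat 2 gave 541, 554 or 511. The short-transcript index as a covariate gave 1480 genes, day 0 counted as 1 sample 558, and 276 changed by at least 1 on the log2 scale. From day 4 to day 5, 102 genes changed (58 higher, 44 lower). Comp rose 8.40-fold (log2 3.07, SE 0.29, adjusted p = 1.09e-05), Lypd6 rose 4.92-fold, Aqp12 was at least 2.98-fold higher, and Amh (−2.04), Tmem106b (−1.84) and, at least 2.95-fold, Slc12a8 were lower. Amh was not called in this step with the authors' values, which gave −0.68 (adjusted p = 0.0861), or with a fit to the compared days (adjusted p = 0.13, the highest of a range from 0.00148). Aqp12 was not called with a fit to the compared days (adjusted p = 0.101, the highest of a range from 2.83e-06). The count was 50 under median scaling, 17 with a fit to the compared days, and 51, 63 and 57 without day 4 repeat 1, day 5 repeat 1 and day 5 repeat 2. It was 200 with array weights, 233 with the short-transcript index and 47 with day 0 counted as 1 sample, and 51 genes changed by at least 1.

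From day 5 to day 6, 143 genes changed (76 higher, 67 lower). Comp (2.09), the zinc-finger factor Klf1 (2.02) and H2-K2 (1.62) rose, Chac1 (−1.84) fell, and Sectm1b and Aqp12 at least 2.87-fold and at least 3.01-fold lower. The fall of Sectm1b was not called with the authors' values (adjusted p = 0.0732, within 0.000446 to 0.286 over all alternatives). With limma fitted to the arrays of days 5 and 6 alone, 0 genes passed and 779 had an unadjusted p under 0.05. Median scaling gave 85 genes (67 higher, 18 lower), and leaving out day 5 repeat 1, day 5 repeat 3, day 6 repeat 2 or day 6 repeat 3 gave 66, 49, 218 or 75. Array weights gave 246 genes, the repeat number as a block 81 and day 0 counted as 1 sample 38, and 46 changed by at least 1. From day 6 to day 8, 82 genes changed (51 higher, 31 lower). Sectm1b was at least 12.9-fold higher, Aldh1a7 (2.60) and Ibsp (2.39) rose, Sspn was at least 6.44-fold lower, and Erdr1 (−1.84) and Klf1 (−1.73) fell. Erdr1 did not pass without day 6 repeat 1 (adjusted p = 0.0607), without day 8 repeat 1 (adjusted p = 0.122) or in 4 other alternatives, within a range of 0.000569 to 0.465. A fit to the compared days gave 3 genes and ended the calls of Ibsp (adjusted p = 0.0628, within 2.26e-07 to 0.0628) and Klf1 (adjusted p = 0.144, within 7.36e-05 to 0.144). The authors' values gave 128 genes and median scaling 48 higher and 11 lower, and leaving out day 6 repeat 2, day 8 repeat 1 or day 8 repeat 3 gave 51, 33 or 47. Array weights gave 254 genes, the short-transcript index 146, the repeat number as a block 46 and day 0 counted as 1 sample 23, and 39 changed by at least 1.

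Genes that had changed by day 2 were mostly still changed at day 8. Of 1293 genes risen at day 2 and 2197 risen at day 8, 918 rose on both days, where independent lists of these sizes would share 266. Of 1395 and 2440 fallen genes 1070 fell on both, against 318. A rise at day 2 with a fall at day 8 was seen for 65 genes, and the opposite for 41. Both comparisons share the day 0 arrays. With day 0 counted as 1 sample 179 genes rose and 211 fell on both days, with array weights 1591 and 1667, and 190 and 229 with a change of at least 1 on the log2 scale. With day 0 split so that each comparison had its own 2 or 3 day 0 arrays (10 splits), 536 to 606 genes rose and 648 to 724 fell on both days. Across genes, which are not independent replicates, the log2 changes at day 2 and day 8 correlated at 0.688 against a mean of 0.376 in 100 simulated sets of unchanged days that shared the day 0 arrays, and at 0.613 to 0.675 with day 0 split. If the day 0 arrays are repeats of 1 pool, both parts of a split share that pool. The splits then do not remove the shared baseline, and the simulated sets, which drew each array independently, do not allow for it.

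The arrays labelled brain reference were compared with day 0 as a check of the labels. Of 10498 genes tested, 8664 differed, 3924 higher and 4740 lower on the labelled arrays. All 24 oocyte genes were lower there, with a median of −6.72, and 14 of 15 antral granulosa genes were lower and 1 higher. Gdf9, Ooep and Inha differed by −9.10, −9.12 and −9.07. All 14 macrophage markers, all 13 endothelial markers and all 6 red blood cell genes were higher, with medians of 4.44, 3.05 and 3.83. Of 16 brain list genes on the array, 10 were detected on none of the 5 labelled arrays. Of the 7 that passed the filter and were tested, 5 were higher, among them Slc17a7 (3.39), Camk2a (2.84) and Stmn2 (1.93), and 2 were lower, among them Aldoc (−0.86).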

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

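No test of this part was chosen after its result was seen: the same test for a lone array was applied to the 5 day 0 arrays for each named gene and list. A value was picked out where the gap between the highest or lowest array and its nearest neighbour exceeded 0.71 of the range of the group, which chance alone gives in about 1 of 20 groups. Of 295 values tested, 20 met this, a share not far above that given by chance, so a single value picked out carries little weight. In 14 of the 20, day 0 repeat 4 was the array apart. On day 0 repeat 4, respiratory chain and ribosomal protein genes lay at a median of −0.341 and −0.124 from the mean of the other day 0 arrays. Among the follicle arrays only day 6 repeat 1 was lower for these 2 sets of genes. No explanation for day 0 repeat 4 was tested.

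Day 0 repeat 4 was above the other 4 arrays for 9 genes. The glycolytic enzyme Eno1 stood at 12.38 against 11.37 to 11.52 and the phosphofructokinase Pfkp at 8.965 against 7.849 to 8.112. The chemokine Cxcl10 stood at 9.952 against 8.774 to 8.915, and H2-K2 at 6.304 against 5.627 to 5.733. Mycl stood at 11.38 against 10.88 to 11.00, Xbp1 at 13.24 against 12.90 to 12.97, Zp3 at 12.44 against 12.05 to 12.13, Ccng1 at 9.333 against 9.037 to 9.116 and Col4a1 at 12.62 against 12.36 to 12.40. The same array was below the others for Ccl4 (9.087 against 9.56 to 9.726), Vegfa (11.36 against 11.65 to 11.77), Thy1 (8.77 against 9.005 to 9.094), Agrn (10.98 against 11.12 to 11.16) and Tmem106b (6.807 against 6.92 to 6.961).

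The other 6 values had another day 0 array apart. Day 0 repeat 3 was above the others for Dusp1 (11.88 against 11.70 to 11.73) and Rgs2 (8.425 against 8.209 to 8.261) and below them for Upk3b (6.875 against 7.105 to 7.196). Day 0 repeat 5 was above the others for Myh11 (7.621 against 7.343 to 7.399) and below them for the mean of the YAP target list (7.812 against 7.858 to 7.872). Day 0 repeat 1 was above the others for Ces3 (6.129 against 5.846 to 5.901).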

How the results depend on the processing

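The alternatives with the short-transcript index as a covariate and without day 6 repeat 1 and day 0 repeat 4 together were chosen after the data were seen, and the others were planned. Of 566 results for named genes and lists, 405 were called, and 0 of these changed sign under any alternative run. Of the 161 not called, 39 changed sign under at least 1 alternative, in 102 comparisons, and 0 of these were called there. Over all alternatives, 2568 comparisons of lists and 17154 of genes kept their side of the threshold, 48 and 198 lost the call, and 2 and 214 gained it. Of the counts of genes and lists, 520 stayed within 1.5 times and 57 did not, and where the construction of an alternative does not give the reason, the cause was not tested. A block for the slide was not run, since no slide was given in the sources used here.

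Median scaling gave 50 genes for day 5 against day 4 and 85 for day 6 against day 5, and the authors' values gave 128 for day 8 against day 6. The repeat number as a block gave 81 for day 6 against day 5 and 46 for day 8 against day 6. Array weights gave 4802 genes for day 2 against day 0, 3885 for day 8 against day 2, and 2321, 200, 246 and 254 for the steps from day 2 to 4, 4 to 5, 5 to 6 and 6 to 8, with 1591 risen and 1667 fallen on both day 2 and day 8.

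A required log2 change of at least 1, which can only lower a count, left 615, 1152, 1323, 1632 and 1749 genes for days 2, 4, 5, 6 and 8 against day 0, 885 for day 8 against day 2, and 276, 51, 46 and 39 for the 4 steps, with 190 risen and 229 fallen on both day 2 and day 8. Fitting only the compared days, which leaves fewer arrays to estimate the spread, gave 578, 17, 0 and 3 genes for the 4 steps in limma, with 779 at an unadjusted p under 0.05 where the count was 0. Day 0 counted as 1 sample, which also leaves fewer samples, gave 498, 1175, 1398, 1938 and 2113 genes for days 2, 4, 5, 6 and 8 against day 0, 558, 47, 38 and 23 for the steps, 179 risen and 211 fallen on both days, and 2662 over the 6 days. The short-transcript index as a covariate gave 1480, 233 and 146 genes for the steps from day 2 to 4, 4 to 5 and 6 to 8.

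Leaving out 1 array at a time gave 511 (without day 4 repeat 2) to 1173 (without day 6 repeat 1) genes from day 2 to day 4, 51 (without day 4 repeat 1) to 145 (without day 6 repeat 1) from day 4 to day 5, 49 (without day 5 repeat 3) to 218 (without day 6 repeat 2) from day 5 to day 6, and 33 (without day 8 repeat 1) to 95 (without day 4 repeat 3) from day 6 to day 8. The other arrays that moved a step by more than 1.5 times were day 2 repeat 2 (541) and day 2 repeat 3 (554) from day 2 to day 4, day 5 repeat 1 (63) and day 5 repeat 2 (57) from day 4 to day 5, day 5 repeat 1 (66) and day 6 repeat 3 (75) from day 5 to day 6, and day 6 repeat 2 (51) and day 8 repeat 3 (47) from day 6 to day 8. The larger comparisons stayed within 1.5 times: 2013 to 3226 genes for day 2 against day 0, 4056 to 5101 for day 8 against day 0, 1844 to 2869 for day 8 against day 2 and 4836 to 5822 over the 6 days.

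Signal over background limits genes near the floor, for which a fold is given as a lower bound. Without a filter on dim probes the brain list was no longer called for day 2 against day 0 (adjusted p = 0.105, from 0.00339 to 0.105 over all alternatives).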

Other observations

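All tests of this part were chosen after the result was seen, except the counts over other splits of the arrays; the short-transcript index used as a covariate was chosen after the data were seen as well, but the bound it had to meet for the oocyte genes was written before that value was computed.

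The timing of 3 lists was followed across the days. The mean change of the cell cycle list from day 0 was 0.24 at day 2, 0.34 at day 4, 0.14 at day 5, −0.36 at day 6 and −0.66 at day 8. At day 4 the cell cycle list was above day 0, with 9 of 27 genes higher and 1 lower (10 and 1 adjusted over the list alone; median 0.31, camera adjusted p = 0.00386). From day 5 to day 6 it fell in 4 of 27 cases with none rising (16 adjusted over the list alone; median −0.49, camera adjusted p = 4.52e-15), and from day 6 to day 8 in 1 (3 adjusted over the list alone; median −0.29, camera adjusted p = 1.00e-06).

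Theca genes went the other way in the step from day 5 to day 6. In that step 2 of 13 rose and none fell (7 adjusted over the list alone; median 0.55, camera adjusted p = 3.90e-06), and Cyp11a1 stood at 8.44 at day 5, 9.43 at day 6 and 9.99 at day 8, with Cyp17a1 at 11.61, 12.55 and 12.71. Immediate early genes rose in the same step in 5 of 18 cases with none falling (7 adjusted over the list alone; median 0.51, camera adjusted p = 3.11e-08, adjusted p = 0.0439 with an estimated correlation), with Fos at 12.20 at day 5 and 13.40 at day 6 and Dusp1 at 10.45 and 11.54. The protocol gave 2 days between medium changes, so the time since fresh medium may differ between day 5 and day 6. A part of this in the shifts was not tested, nor was whether the shifts are linked.

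The arrays labelled brain reference carried few neural transcripts. Genes found at the top of the comparison with day 0 were Nppa (10.44), Myl3 (10.39), Myl2 (10.32), Actc1 (10.24) and Myh6 (9.99), which encode heart muscle proteins, and a heart muscle list written after they were seen had a median percentile of 99.5 among 17914 genes on these arrays, against 30.3 at day 0. Of its 17 genes, 16 were detected on all 5 labelled arrays, Myl3 at 15.23 and Nppa at 15.12, and 5 on all day 0 arrays, while fast skeletal muscle, liver and spleen lists stood at 40.5, 34.5 and 38.0. The brain list stood at 35.6 with 10 of 16 genes detected on none of the 5 arrays, below the bound of 75 set for brain RNA with heart RNA mixed in, and the share of probes detected on these arrays was 0.897 times that on follicle arrays, above the bound of 0.8 set for dim arrays. RNA of heart muscle under another label may therefore be what these arrays hold, and no biological explanation was tested.

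Day 6 repeat 1 stood apart from the other follicle arrays. Each array was set against the mean of the other arrays of its day. On day 6 repeat 1, genes spanning under 3000 bases (698 of those tested) lay −0.474 from the other genes, where the other arrays lay between −0.154 and 0.302. The value of 0.302 is that of day 6 repeat 3, whose reference includes day 6 repeat 1. Its respiratory chain genes lay at a median of −1.61 on day 6 repeat 1, where the lowest other array, day 0 repeat 4, lay at −0.341. The oocyte genes of day 6 repeat 1 were low as well, with a median of −0.67 where the lowest other array lay at −0.36. Less oocyte RNA in the pool as the whole cause is argued against by ribosomal protein genes, whose median change of −0.84 (lowest other array −0.124) exceeded that of the oocyte genes, and a part in it stays open. Uneven recovery of short transcripts may account for the array. However, the genomic span of a gene is not the length of its transcript. Ribosomal protein and respiratory chain genes also fell by more than the short-span gap, so a shift of these gene classes cannot be told apart from it. An array of another day as the whole cause is argued against by its distance to the nearest array, day 8 repeat 3, which was 0.578 where other arrays of the same cultured day lay 0.264 to 0.503 apart; this bound was set after the value was seen. A wrong label together with uneven recovery stays open, and no biological explanation was tested.

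Oocyte genes fell during culture, and dilution of oocyte RNA by growing somatic cells as the whole cause would have them fall alike. The SD of their changes at day 8 over the median standard error was 3.08 for 18 bright genes (SD 0.594, median standard error 0.193), but 1.73 for 17 without Sohlh1, so it rests on 1 gene; the rule that no single gene should carry it was added after the value was seen. Dilution and a loss within the oocyte cannot be told apart here, since a single gene decides the test. With the short-transcript index as a covariate the median fall at day 8 was −1.95, as it was without. This argues against uneven recovery of short transcripts as its cause only as far as that index, made of ribosomal protein and respiratory chain genes, follows it. Only 2 genes of the oocyte list span under 3000 bases, so the index had little to act on through gene length. A change with the day of culture itself stays open as untested.

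Other splits of the arrays into groups of the same sizes were compared with the real one, with the day 0 arrays counted as separate samples. If the day 0 arrays are repeats of 1 pool, too few separate samples are left, and splits against day 0 cannot exclude chance. With the day 0 arrays as separate samples, chance can be excluded for the genes changed at day 2 (1 of 56 splits gave as many; 2688, highest other 9), day 4 (1 of 56; 3606, highest other 5), day 5 (1 of 56; 3841, highest other 5), day 6 (1 of 56; 4586, highest other 13) and day 8 against day 0 (1 of 56; 4637, highest other 32). The lists called at day 2 met the bound (2 of 56, a share under 0.05), but another split called the same number (15, highest other 15). That count alone does not exclude chance. Nor can chance be excluded for the number of lists called at day 8 against day 0 (8 of 56; 14, highest other 15). With all arrays as separate samples, chance can be excluded for genes over the 6 days (1 of 100 regroupings; 5339, highest other 5) and for the arrays labelled brain reference (1 of 100; 8664, highest other 0). The arrays labelled brain reference are titled as repeats too and may hold 1 RNA. If these or the day 0 arrays are repeats of 1 RNA, the regroupings that include them cannot exclude chance. The 10 splits of 3 against 3 arrays are too few for a share under 0.05: the real values were 2396 genes and 14 lists for day 8 against day 2 (highest other 0 and 11), and 897, 102, 143 and 82 genes for the 4 steps (highest other 106, 5, 1 and 4).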
